A study of Sorghum bicolor with 14 samples.

How the data were processed

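RNA of 12 sorghum libraries and bisulfite-treated DNA of 2 root libraries were used, with 1 library per group. Seedlings were kept in day lengths of 12 hours and greenhouse plants in 14 hours, per the labels. Per the labels, 3 groups of 10 plants were harvested in each seedling treatment, and flowers of 6 to 8 plants were pooled, but each group came as 1 library. The labels give the NaOH treatment as 0.2 M and do not say whether this was the concentration at the roots or that of a stock.

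Per the labels' protocols, RNA was read as single-end, non-strand-specific reads of 51 bases, and bisulfite-treated DNA as paired reads of 50 bases. Per the submitters' processing notes, the RNA tools were CASAVA 1.5, Bowtie, TopHat and Cufflinks 0.8.1. The deposited RNA files give an FPKM per transcript with the bounds of its interval, for 2 sets of gene models, a reference set of 34079 genes and a larger set named GB2 with 77318 models. The score column of the deposited gene model files, a whole number for a transcript relative to the main isoform of its gene, was not used here. The deposited bisulfite files give a count of methylated and a count of unmethylated reads per cytosine, with its strand and context, and the deposited level equalled the ratio of these counts within 0.0001 at every cytosine listed in either file. The aligner and caller of the bisulfite reads are not given in the sources used here, nor is the genome build.

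The bisulfite files list cytosines that are upper-case in their sequence, so cytosines in soft-masked repeats are absent. Some contexts with a lower-case base that read CG or CHG when upper-cased were given as CHH, and the context was therefore taken from the upper-cased sequence, which moved 0.0434% of listed cytosines in the NaOH library and 0.0435% in the ABA library. The match of the bisulfite coordinates to the gene models was checked at intron ends: 99.7% of 49702 listed cytosines there were followed by T on the strand that splicing needs, against 26.3% of listed cytosines overall.

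The FPKM of a gene was the sum over its transcripts, and interval widths were added in quadrature. Reads behind an FPKM were recovered from the interval, which spans 2 SDs of a Poisson count: 78.1% of 88990 values of single-transcript genes under 50 reads came out whole within 0.05. Mapped reads per library were taken from the ratio of coverage to FPKM. Genes were compared on log2(FPKM + 1), which understates the change of low genes. The size rule was a fold of at least 2, an FPKM of at least 1 in 1 of the 2 libraries, and intervals that do not overlap. With 1 library per group no test of 1 treatment against its own control was possible within an organ. Across organs, limma (3.58.1, R 4.3.3) was fitted to log2(FPKM + 1) of 22643 genes at 1 FPKM or more in at least 2 of the 8 seedling libraries, with treatment and organ as factors, 3 residual degrees of freedom, a mean-variance trend and Benjamini-Hochberg adjustment. It was fitted again with NaOH and H2O as 1 control group (4 residual degrees of freedom). Both fits take root and shoot as independent, which the labels do not state. Within each organ it was fitted with NaOH and H2O as 1 control group to genes at 1 FPKM or more in any of the 4 libraries (21256 in roots, 20294 in shoots), with 1 residual degree of freedom. There the error is the difference of the 2 control libraries, so any shift of a treated library counts as a change. The limma fits were chosen after the data had been seen. The same rule was applied to 7 pairs of libraries. Overlaps are set beside the product of the list sizes over the genes tested in both. The reads of microRNA precursors were compared as ratios with exact conditional binomial intervals, for precursors with 10 or more reads in the 2 libraries together. The median of the precursor list is given as a percentile among 10000 random lists matched within 100 ranks of mean expression.

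Methylation levels are methylated read calls over all read calls at cytosines with at least 4 reads, with 95% Wilson intervals. Genes were compared over cytosines with at least 4 reads in both libraries, where at least 10 were shared, and chance was simulated in 100 draws at the observed depths. At the CG cytosines with at least 4 reads, the mean coverage was 5.08 reads in the NaOH library and 4.97 in the ABA library. Over all listed nuclear CG cytosines it was 2.34 and 2.28. The minimum of 4 reads kept 2473388 of 13145192 CG cytosines in the NaOH library and 2443191 of 13968902 in the ABA library. Profiles used flanks of 2000 bases in bins of 100 and gene bodies in 20 parts. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals and simulated draws also take calls on the same read as independent, which can make their ranges too narrow.

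The settings, the pairs of libraries and the rule for named genes were chosen before the data were examined. The rule was to name described genes with the largest change. The reference gene table has 32945 genes and matched 0 of the 34079 IDs, so the fallback of the rule applied: at most 2 IDs per direction with the largest change among genes at 5 FPKM or more with separate intervals, 1 per tissue, and 3 GB2 models. The gene lists by description had no members for the same reason, and the 2 lists given by ID rest on names that the files do not pair with them, so neither kind is reported. The microRNA precursors, which the files name, were taken as a list after the data had been seen, and those named individually were chosen from precursors whose interval left out 1 or with high reads. Named genes were also looked up in the GB2 models after the data had been seen: of 28 named differences, 19 were past the size rule there in the same direction, 3 were not, and 6 were of genes without a GB2 model. Genes with opposite changes in root and shoot, and genes listed at 0 in a single seedling library of an organ, were also chosen after their values were seen.

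The size rule was tested on simulated data: 200 of 34079 genes of the root NaOH library were changed by known folds and Poisson counts drawn at the depth of the root ABA pair. The rule recovered 0 of 50 genes changed by 1.5-fold, 50 of 50 changed by 3-fold, 49 of 50 by 4-fold and 50 of 50 by 8-fold, and called 6 unchanged genes. With data simulated for the other pairs, unchanged genes called numbered 13 in shoot PEG against H2O, the most, and 11 in shoot NaOH against H2O. The limma fit, on simulated data with 50 genes changed at each size, recovered 3 changed by a log2 of 1, 30 by 2, 43 by 4 and 50 by 8, with 12 unchanged genes called. With 1 control group it recovered 12, 37, 47 and 50, with 7 unchanged genes called. Within roots it recovered 0, 0, 16 and 32, with 1 unchanged gene called, and within shoots 0, 0, 15 and 26, with 0 unchanged genes called. The data simulated for limma held no shift of a whole treated library, so they do not measure false calls from such a shift. The alternatives tried were other pseudocounts, FPKM minimums, folds, scalings, control libraries, gene models, coverage minimums and region definitions. The alternatives planned for files that give reads without calls, which were other read scalings and a mapping score limit, did not apply, since the bisulfite files give calls. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (Wilson intervals) and matplotlib 3.10.9.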

Results

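The series measured messenger RNA in 12 libraries of Sorghum bicolor genotype BTx623 and cytosine methylation in 2 bisulfite libraries of roots. Of the RNA libraries, 4 came from greenhouse plants (embryos, vegetative meristems, floral meristems and flowers) and the others from roots and shoots of hydroponic seedlings aged 9 days. The seedlings had been treated from day 8 with 20 µM abscisic acid (ABA, a hormone of water stress and seed maturation), 20% polyethylene glycol (PEG, an osmolyte that lowers water availability), NaOH or H2O. ABA, PEG and NaOH were applied for 27 hours. NaOH served as the control for ABA and H2O as the control for PEG. The bisulfite libraries came from ABA and NaOH roots. Each group held 1 library, so no difference between 2 libraries given here has a replicate check. Intervals are 95% intervals of counting error. Mapped reads, recovered from the files, numbered 11325528 in embryo, the fewest, and 78382689 in root H2O, the most. Genes at an FPKM of 1 or more (fragments per kilobase of transcript, scaled to mapped reads) numbered 17404 in embryo, the lowest count, and 21208 in flower, the highest. The bisulfite libraries held 125355124 read calls over 61362605 cytosines (NaOH) and 141237308 over 69849311 (ABA). A gene is called higher or lower here if (FPKM + 1) differed by at least 2-fold between 2 libraries, its FPKM was 1 or more in 1 of them, and its intervals did not overlap. Genes are given by ID, because the files name only the microRNA precursors. Coordinates are those of the gene model files. Values are from the reference gene models unless GB2, a larger set of models, is named.

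The NaOH and H2O libraries, which received neither ABA nor PEG, show how far a pair of control libraries differed. In roots, 211 of 20760 genes were higher in NaOH than in H2O and 32 were lower. In shoots, 22 of 19451 were higher and 19 lower, where simulated data of that pair gave 11 unchanged genes past the rule from counting error alone. Sb02g005750 (chromosome 2, 6810247 to 6812784) was at 48.1 FPKM in NaOH roots (interval 46.2 to 50.1) and 0.374 in H2O roots (0.221 to 0.527), a log2 change of 5.16. Sb02g038760 was at 213 FPKM in NaOH roots and listed at 0 in H2O roots, and its level was 2.15 or less in the ABA and PEG roots (61.1 and 0.102 FPKM in NaOH and H2O roots with GB2). Sb05g003480 fell from 11.0 FPKM in H2O roots to 2.16 in NaOH roots (28.7 to 3.36 with GB2), and Sb06g029525, with 20 reads in H2O roots, was at 51.3 and 6.74. In shoots, Sb03g029170 was at 877 FPKM in NaOH (870 to 885) and 264 in H2O (260 to 269), and Sb02g004390 at 12.7 and 3.36. Sb09g019930, at 5684 FPKM in H2O shoots, and Sb08g017816, with 5 reads there, were listed at 0 in NaOH shoots. With GB2 the differences of 3 of these genes were lost. Sb06g029525 and Sb02g004390 were below 1 FPKM in both libraries of their pairs, and Sb08g017816 was at 0.993 FPKM in NaOH and 1.28 in H2O shoots. Sb09g019930 was at 0 in NaOH shoots with both sets, and Sb02g005750 and Sb03g029170 have no GB2 model. Across genes, the spread of FPKM differences, each scaled by its own counting error, was 2.68 times that of counting error in roots and 2.54 times in shoots.

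The ABA libraries ask which genes respond to the hormone. ABA-treated roots differed from NaOH roots more widely than any other of the 7 pairs, with 1187 of 21302 genes higher and 2201 lower. The spread of FPKM differences, scaled in the same way, was 7.60 times that of counting error. Sb09g027110 (chromosome 9, 56214055 to 56215358) rose from 1.18 FPKM (interval 0.879 to 1.48) to 3777 (3762 to 3792), a log2 change of 10.76 (2186 FPKM in ABA roots and 10.32 with GB2). Sb07g023790 rose from 0.150 FPKM, 6 reads, to 1990 (1978 to 2002), also by 10.76. Sb06g024780, a root gene at 772 FPKM in NaOH (763 to 782), fell to 4.95 (4.25 to 5.65), a log2 change of -7.02. Sb02g022733 was at 519 FPKM in NaOH roots and listed at 0 in ABA roots. Against the H2O root library, 1308 genes were higher and 1726 lower in ABA, and 1070 higher and 1563 lower were called against both controls. The ratio of lower to higher genes was 1.85 against NaOH and 1.32 against H2O. With NaOH and H2O roots as 1 control group, limma called 2415 genes higher and 3215 lower with ABA at an adjusted p under 0.05; its error comes from the difference of those 2 control libraries alone, and the fit was chosen after the data had been seen.

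In ABA-treated shoots, 841 of 19875 genes were higher than in NaOH shoots and 715 lower. Sb09g018420 (chromosome 9, 46038022 to 46039089) rose from 3.34 FPKM (interval 2.79 to 3.88) to 773 (764 to 781), a log2 change of 7.48. The same gene was at 6585 FPKM in ABA roots and 118 in NaOH roots. Sb04g030510 fell from 80.2 FPKM (72.8 to 87.6) to 2.89 (1.45 to 4.34), a log2 change of -4.38 (12.4 to 0.468 FPKM and -3.18 with GB2), and Sb02g005350 fell from 16.7 to 0.392, a log2 change of -3.67. Sb09g019930 was at 4574 FPKM in ABA shoots and listed at 0 in NaOH shoots, but at 5684 in H2O shoots, so its difference lies in the NaOH library. The median gene lay 0.11 above 0 on the log2 scale. Higher genes made up 54.0% of the calls, against 41.4% (671 higher, 948 lower) with upper quartiles set equal and 42.8% (686 higher, 916 lower) with median ratios set equal. The limma fit within shoots, with the same limits, called 2645 higher and 2154 lower.

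PEG asks which genes respond to lower water availability. In PEG-treated roots, 937 of 21186 genes were higher than in H2O roots and 281 lower. Sb03g029390 rose from 0.298 FPKM, 1 read, to 44.9 (interval 36.6 to 53.3), a log2 change of 5.14 (14.3 FPKM in PEG roots and 3.89 with GB2). Sb02g005750 rose from 0.374 FPKM to 43.1 (41.2 to 45.0) in PEG roots, but its level in NaOH roots was 48.1. Sb05g026950 and Sb05g026980, which lie near each other on chromosome 5, fell from 120 FPKM (117 to 124) to 2.25 (1.76 to 2.73) and from 117 (114 to 120) to 2.20 (1.71 to 2.69). Their log2 changes were -5.23 and -5.20. Their reads came out as multiples of 0.5, so reads shared between them cannot be assigned to either gene with certainty. With the NaOH root library as the control, 572 genes were higher in PEG and 373 lower, so higher genes made up 60.5% of the calls in place of 76.9%. The limma fit within roots held 1 PEG library, and its error came from the difference of the NaOH and H2O libraries alone. Its calls therefore do not measure variation between plants.

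In PEG-treated shoots, 874 of 20209 genes were higher than in H2O shoots and 264 lower. Sb09g018420 rose from 3.19 FPKM (interval 2.62 to 3.75) to 893 (884 to 902), a log2 change of 7.74, and Sb09g027110 from 0.894 (0.621 to 1.17) to 547 (541 to 553), a log2 change of 8.18. Sb03g046090 fell from 137 FPKM (134 to 140) to 1.90 (1.56 to 2.24), a log2 change of -5.57. Sb07g005140 fell from 23.4 FPKM to 0.912, a log2 change of -3.68. Both of these were more abundant in roots, at 241 and 243 FPKM in the PEG roots. The median gene lay 0.17 above 0 on the log2 scale. Higher genes made up 76.8% of the calls, against 63.9% (707 higher, 399 lower) with upper quartiles set equal and 60.5% (671 higher, 438 lower) with median ratios set equal. The limma fit within shoots held 1 PEG library, and its error came from the difference of the NaOH and H2O libraries alone. A shift of the whole PEG library, such as that of the median gene, counts as a change there. Its calls therefore do not measure variation between plants.

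**Figure D1:**
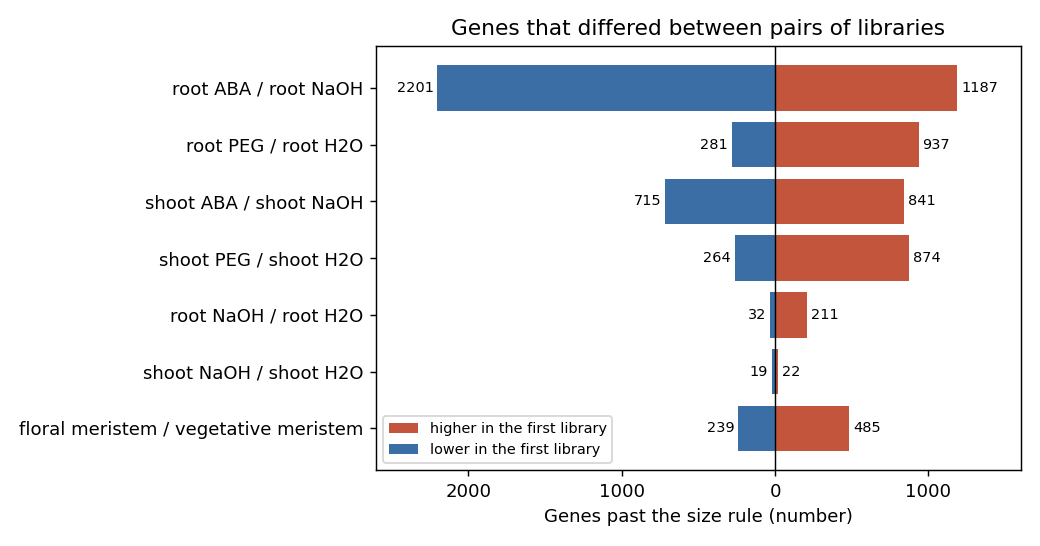
Number of genes past the size rule in 7 pairs of libraries (horizontal axis), to the right where higher and to the left where lower in the first library, with 1 library per group. The root ABA pair holds 1187 and 2201 genes, and the pair of shoot control libraries 22 and 19.

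ABA and PEG, which had separate control libraries, shared many called genes. In shoots, 404 genes were higher in both comparisons, where independent lists of these sizes would share 32.3, and 111 were lower in both, against 9.39. In roots, 299 genes were higher in both, against 43.9, and 171 lower in both, against 28.6. Roots also held 179 genes that were lower with ABA and higher with PEG, against 92.3 for independent lists, and 5 with the opposite pattern, against 13.6. A difference between the control libraries can add to the 179, since 211 genes were higher in NaOH than in H2O roots. Sb02g005750, for example, was at 48.1 and 43.1 FPKM in NaOH and PEG roots, and at 0.374 and 1.27 in H2O and ABA roots. The log2 changes of ABA and PEG correlated across genes with a Pearson r of 0.539 in shoots and 0.284 in roots; genes are not independent replicates. Between root and shoot, 346 genes were higher with ABA in both organs, against 39.1, and 216 lower in both, against 36.8. With PEG, 273 were higher in both organs, against 27.6, and 28 lower in both, against 2.11. A limma fit over the 8 seedling libraries, with organ as a block in place of replicates and chosen after the data had been seen, called 5 of 22643 genes higher and 0 lower with ABA against NaOH at an adjusted p under 0.05, and 2050 and 1758 at an unadjusted p under 0.05. Sb03g043410 led them, with a log2 change of 6.10 (limma adjusted p = 0.00649). The same gene was the 1 called higher with PEG against H2O (log2 change 4.62, limma adjusted p = 0.0296), where limma called 0 lower and 1427 and 391 at an unadjusted p under 0.05. With NaOH and H2O as 1 control group, limma called 564 higher and 441 lower with ABA, and 4 higher and 0 lower with PEG (1965 and 572 at an unadjusted p under 0.05). The labels do not say whether root and shoot came from the same plants, so the organs are not known to be independent. A set of 121 genes was higher and a set of 6 lower in the 4 treatment comparisons. Sb09g018420 and Sb09g027110 were among the named genes of more than 1 comparison. Sb09g027110, highest in ABA roots, was also at 1510 FPKM in untreated embryos.

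The tissue libraries ask which genes mark each organ. Genes at 10 FPKM or more and at least 8 times the level (FPKM + 1) of each other tissue numbered 706 in flower, 507 in root, 246 in shoot, 210 in embryo, 9 in floral meristem and 1 in vegetative meristem. Root and shoot are represented by the H2O seedlings. Each meristem had to exceed the other meristem as well, with which it correlated at 0.987, so the counts are not comparable across tissues. The most abundant of them were Sb06g024350 in embryo (9778 FPKM, at most 6.22 elsewhere), Sb09g021340 in flower (3390, at most 0.593) and Sb04g021205 in root (2504, at most 8.30; with GB2 583, at most 0.758). In shoot it was Sb07g005660 (8835 FPKM, at most 1093 elsewhere, in flower), and in floral meristem Sb03g006870 (617, at most 74.3, in embryo). The 1 gene of the vegetative meristem is a microRNA precursor. The meristem libraries correlated with each other at 0.987 and with embryo at 0.881 and 0.880, the highest values that embryo reached with any library.

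The floral and vegetative meristems are the closest pair of tissues. Of 19052 genes, 485 were higher in the floral meristem and 239 lower. Sb09g018420 was at 238 FPKM in the floral meristem (interval 232 to 245) and 1.11 in the vegetative meristem (0.666 to 1.55), a log2 change of 6.83. Sb03g006870 was at 617 FPKM (605 to 629) and 9.53 (8.07 to 11.0), a log2 change of 5.87. Both genes were also higher in ABA roots and shoots than in the NaOH controls. Sb03g006870 was at 193 FPKM in ABA roots and 1.39 in NaOH roots, and at 134 in ABA shoots and 17.1 in NaOH shoots. Sb03g005285 and Sb07g025990, with 6 and 9 reads in the vegetative meristem, were listed at 0 in the floral meristem. With GB2, Sb07g025990 was at 0.358 and 1.81 FPKM in the floral and vegetative meristems.

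Some microRNA precursors differed in reads between organs, with 1 library per group and no test of the precursors as a group between organs. The precursor sbi-MIR159, of a family that targets GAMYB factors, had 447 reads in the floral meristem (14.9 RPM, reads scaled to mapped reads) and 241 in the vegetative meristem (7.98), a ratio of 1.87 (interval 1.59 to 2.19). With its GB2 model the log2 change was 0.13, against 0.90 with the reference model. Its level was 1.72 or less in the other libraries. The precursor sbi-MIR172b, of a family that targets AP2 factors and promotes flowering, went the other way, with 34 and 61 reads and a ratio of 0.561 (0.358 to 0.868). As a list, 29 precursors had a median log2 change of 0.74 in the floral against the vegetative meristem, above each of 10000 random lists matched on expression (range on resampling the precursors, 0.23 to 0.95). With the GB2 models, which hold 10 of these 29, the median in the floral against the vegetative meristem was 0.19, at percentile 70.2. The random lists were matched on FPKM and not on reads or model length, so the percentiles do not allow for precursors with few reads. Extreme percentiles also occurred in a pair of control libraries: in NaOH against H2O shoots the median of 37 precursors was -0.15, at percentile 0. In PEG against H2O roots it was 0.28, at percentile 99.9, but -0.16, at percentile 4.95, with the 12 precursors of the GB2 models. The precursor sbi-MIR171a, of a family that targets SCARECROW-like factors, had 132, 104, 74 and 49 reads in ABA, H2O, NaOH and PEG roots, and 7 or fewer in each other library. Of the precursors of miR396, whose targets are growth-regulating factors, sbi-MIR396b was mainly a root transcript (63 reads in H2O roots, 3 in H2O shoots) and sbi-MIR396c a shoot transcript (0 and 19 reads).

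**Figure D2:**
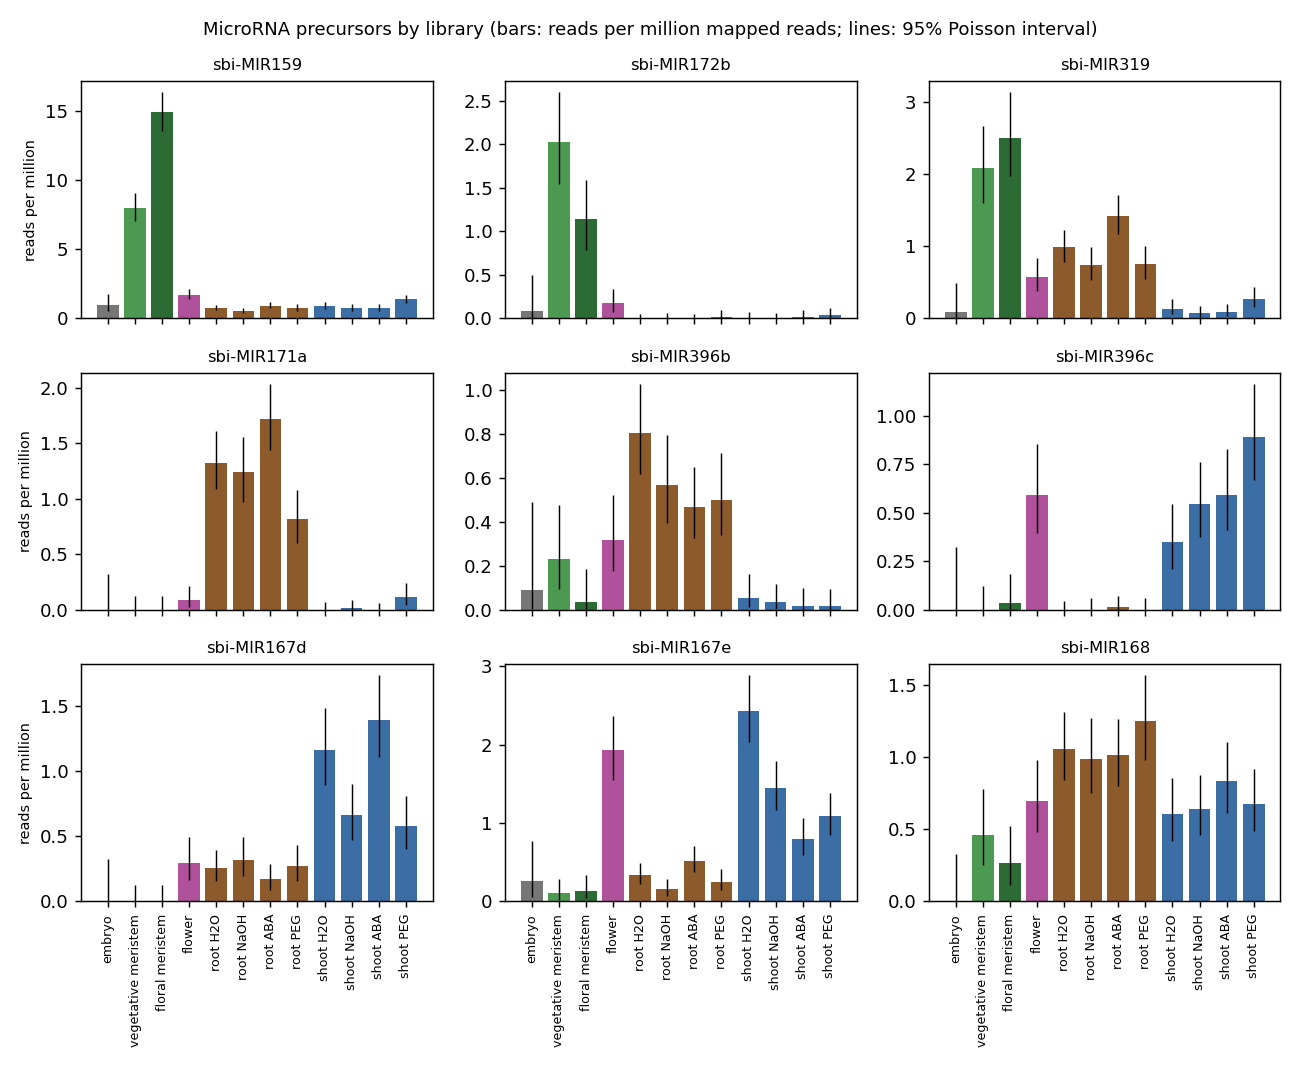
RPM (vertical axis) of 9 microRNA precursors in the 12 libraries (horizontal axis), with 95% Poisson intervals as lines and 1 library per bar. The sbi-MIR159 precursor reached 14.9 in the floral meristem and 7.98 in the vegetative meristem.

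In the seedlings, intervals of the precursor ratios left out 1 for 6 of 19 precursors in ABA against NaOH roots, 7 of 19 in PEG against H2O roots, 5 of 16 in ABA shoots and 4 of 14 in PEG shoots. In the pairs of control libraries they did so for 1 of 22 in roots and 4 of 15 in shoots. With the other control library the counts were 5 of 21 in ABA roots, 3 of 21 in PEG roots, 4 of 16 in ABA shoots and 5 of 16 in PEG shoots. In ABA roots against NaOH roots, sbi-MIR319, of a family that targets TCP factors, had 109 and 44 reads, a ratio of 1.92 (interval 1.34 to 2.79), and 1.44 (1.07 to 1.96) against H2O roots. The precursor sbi-MIR167e, of a family that targets auxin response factors, had 40 and 9 reads, a ratio of 3.45 (1.65 to 8.08), but 1.57 (0.934 to 2.68) against H2O. In ABA shoots, sbi-MIR166a, of a family that targets HD-ZIP III factors, had a ratio of 3.07 (1.45 to 7.05) to NaOH and 2.49 (1.21 to 5.53) to H2O. In shoots sbi-MIR167e was lower in the ABA, PEG and NaOH libraries than in H2O, with ratios of 0.330, 0.449 and 0.596. In PEG roots, sbi-MIR171a had a ratio of 0.617 (0.430 to 0.874) to H2O roots and 0.660 (0.450 to 0.960) to NaOH roots. The precursor sbi-MIR164, of a family that targets NAC factors, had 7 reads in PEG roots and 35 in H2O roots, a ratio of 0.262 (0.0981 to 0.598), but NaOH roots had 11. With its GB2 model the log2 change of sbi-MIR164 was 0.13, against -1.89 with the reference model, and in ABA against NaOH roots that of sbi-MIR167e was 0.58, against 1.67, and that of sbi-MIR319 0.37, against 0.89. For sbi-MIR166a in ABA shoots it was 0.99 to NaOH and 0.40 to H2O, against 1.60 and 1.31. In PEG shoots, sbi-MIR396c had a ratio of 2.55 (1.49 to 4.56) to H2O and 1.64 (1.05 to 2.61) to NaOH (log2 changes with GB2 of 0.70 and 0.59, against 1.32 and 0.70). In shoots against H2O, sbi-MIR167e had log2 changes with GB2 of -0.92, -0.98 and -0.33 in ABA, PEG and NaOH, against -1.58, -1.14 and -0.74. Between 12 and 22 precursors were compared per pair of libraries, so some intervals leave out 1 by chance. The intervals were not adjusted for the number compared.

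Each library was also quantified against a larger set of gene models, GB2. It holds 77318 models: 30324 with the ID of a reference model, 1796 that overlap a reference exon on the same strand under another ID, and 45198 with no reference exon on their strand. Of these 45198, 82.7% had 1 exon, the median length was 422 bases, and 27177 reached 1 FPKM in at least 1 library. The highest in FPKM was model 251027 (18861 FPKM in ABA roots, length 77 bases, on the strand opposite a reference exon). Next were model 207283 (7096 in embryo) and model 209774 (5347 in embryo). Their reads ran the other way, 477 of 76894317 mapped reads in ABA roots, and 1810 and 3723 of 11325528 in embryo. The FPKM of so short a model therefore does not rank it by abundance. Strand was not recorded by these libraries, so reads of a model opposite a reference exon cannot be told from those of the reference gene. CG methylation over the bodies of the 45198 models was 12.8% in NaOH roots, against 8.12% in models that carry a reference ID and 22.2% in the 1796 that overlap a reference exon. Of the 45198, 9512 had enough cytosines for a value of their own (at least 10), and their median was 0.382%.

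In roots, 23.8% of read calls at CG cytosines were methylated in the NaOH library (interval 23.8% to 23.9%, cytosines with at least 4 reads), 14.6% at CHG (14.6% to 14.6%) and 1.12% at CHH (1.11% to 1.12%), where H is A, C or T. The ABA library had 22.9% at CG (22.8% to 22.9%), 13.8% at CHG (13.8% to 13.8%) and 1.29% at CHH (1.28% to 1.29%). The differences, ABA minus NaOH, were -0.983 points at CG, -0.794 at CHG and 0.172 at CHH, each with the same sign on 10 of 10 chromosomes. Chromosome 5 had the highest CG level in NaOH roots, 36.5%, and chromosome 1 the lowest, 16.9%. Over cytosines read at least 4 times in both libraries the differences were -0.549, -0.352 and 0.0955 points. With at least 10 reads per cytosine, the CG difference was 0.0144 points (-0.184 to 0.213) and the CHG difference 0.367 (0.122 to 0.612). The CG level itself also moved with the minimum of reads, by more than its intervals. It was 28.8% in NaOH and 27.5% in ABA roots with at least 1 read per cytosine. With at least 10 reads it was 26.4% and 26.5%. The chloroplast genome, which serves as an unmethylated background, read 0.324% methylated at CHH in the NaOH library and 1.24% in the ABA library, and the mitochondrial genome 0.305% and 0.706%. Subtracting these backgrounds turned the nuclear CHH difference to -0.741 points (chloroplast) and -0.227 (mitochondrial), though exons of ABA roots, at 0.478%, read below both backgrounds. Over gene bodies the CG level, at the cytosines each library covered, was higher in the ABA library, 8.49% against 8.33%. Of those cytosines, more lay in introns in the ABA library (135537 against 131070) and fewer in exons (992523 against 1028689). Cytosines in soft-masked sequence are absent from the files, so repeats are left out of these levels.

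**Figure D3:**
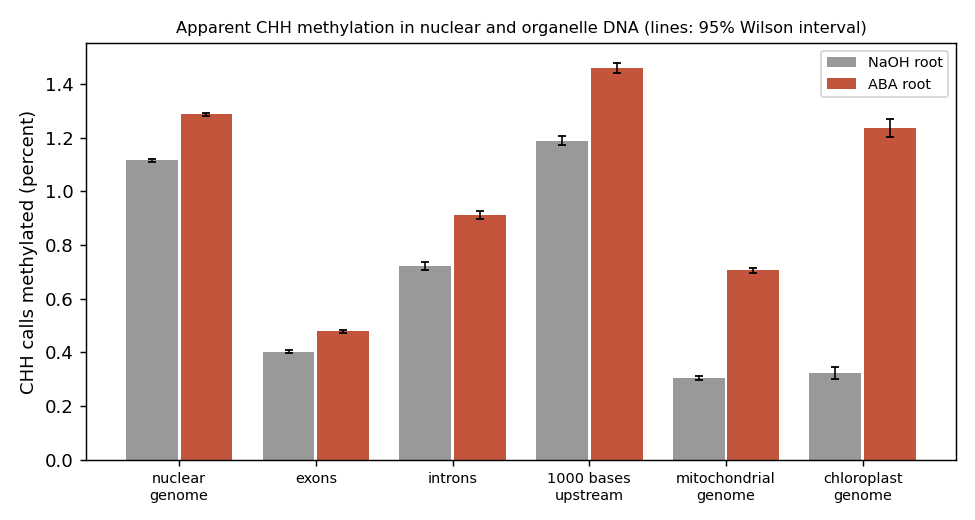
Methylated read calls at CHH cytosines in percent (vertical axis) for the nuclear genome, its exons, introns and upstream regions, and the organelle genomes (horizontal axis), in 1 NaOH and 1 ABA root library, with 95% Wilson intervals. The ABA library is higher in each, 1.29% against 1.12% in the nuclear genome and 1.24% against 0.324% in the chloroplast genome.

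Methylation along genes differed with expression in the matched root library. With read calls pooled over the genes of a class, genes listed at 0 had the highest levels at the gene start. In the first of 20 parts of the gene body their CG level in NaOH roots was 16.4%. It was 4.42% in genes up to 1 FPKM, 1.52% from 1 to 10 and 1.13% over 10. In the middle of the body the order was different, with 19.3% in genes over 10 FPKM and 17.0% in genes listed at 0. Genes from 1 to 10 FPKM stood at 7.86% there and genes up to 1 FPKM at 6.89%. In ABA roots the middle of genes over 10 FPKM stood at 24.1%. Each library was profiled over its own covered cytosines and its own FPKM classes, so 24.1% and 19.3% are not a like-for-like comparison. Over shared cytosines of whole gene bodies, the median CG difference across 12675 genes was 0 points. CHG in the middle of the body was at 12.9% in genes listed at 0 in NaOH roots, 3.96% up to 1 FPKM, 2.10% from 1 to 10 and 2.41% over 10. At CHH, genes over 10 FPKM had the highest level between 2000 and 1500 bases upstream, 1.69% in NaOH and 1.80% in ABA roots. A CG level of 50% or more over the gene body was found in 25.1% of genes listed at 0, 8.55% up to 1 FPKM, 5.38% from 1 to 10 and 7.43% over 10. The median gene body CG level in NaOH roots ran otherwise. It was 0.562% in genes listed at 0, 0.433% up to 1 FPKM, 0.702% from 1 to 10 and 3.52% over 10. Of genes listed at 0, 67.9% were under 5%, so their high pooled levels come from a minority of genes. Introns were more methylated at CG than exons, 32.5% against 5.43% in NaOH roots and 30.6% against 5.65% in ABA roots.

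**Figure D4:**
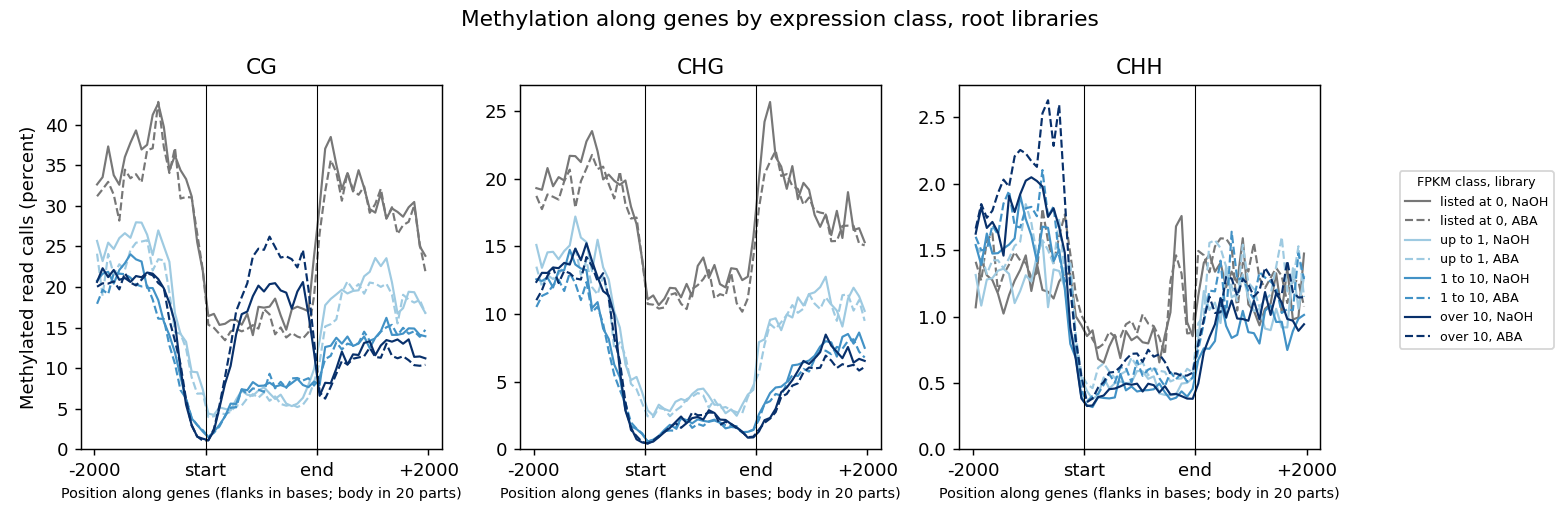
Methylated read calls in percent (vertical axes) at CG, CHG and CHH cytosines from 2000 bases upstream to 2000 bases downstream of genes (horizontal axis, gene bodies in 20 parts), by FPKM class, in 1 NaOH (solid) and 1 ABA (dashed) root library. CG methylation falls to 1.13% at the start of genes over 10 FPKM in NaOH roots and stands at 19.3% in the middle of their bodies.

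Gene by gene, the CG methylation of ABA and NaOH roots was compared over cytosines shared by both libraries, in 12675 genes with at least 10 of them. The SD of the differences across genes was 2.80 points, against 2.26 from counting error alone. A difference of at least 20 points was found in 7 genes with a higher and 15 with a lower level in ABA roots. Counting error alone gave 3.09 and 3.13 on average in 100 simulated draws, and at most 9 and 7. The draws and the intervals take each call as independent, but a read can cover several cytosines of a gene. Calls on the same read can go together, so the simulated counts and SD may be too low and the intervals too narrow. The excess over the draws therefore does not show that methylation differed at these genes. Sb02g005540 was at 94.0% of 83 calls in NaOH roots (interval 86.7% to 97.4%) and 50.8% of 65 calls in ABA roots (38.9% to 62.5%), and Sb01g017905 at 97.8% of 45 calls and 63.0% of 46. In the other direction, Sb02g030240 was at 47.9% of 73 calls in NaOH and 75.5% of 53 in ABA, and Sb08g022120 at 69.2% of 52 and 95.8% of 72. Of these genes, Sb02g030240 had a similar FPKM in both root libraries, 40.4 and 42.2, and the others were listed at 0 in both.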

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

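The tests of CHH and CG methylation, and of the scaling of FPKM values, were chosen after the results were seen; the test with the H2O library as the ABA control was written before its result.

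ABA-treated roots read higher at CHH cytosines than NaOH roots, and so did DNA outside the comparison: in the ABA library, 1.24% of CHH calls in the chloroplast genome and 0.706% in the mitochondrial genome were methylated, above the NaOH library. Organelle genomes should read as unmethylated, so this may reflect incomplete bisulfite conversion, and the mitochondrial difference of 0.400 points exceeds the nuclear difference of 0.172. Subtracting the organelle levels turned the nuclear difference to -0.227 points (mitochondrial) or -0.741 (chloroplast), but exons of ABA roots, at 0.478%, lay below both levels, so these do not measure nuclear conversion directly. Conversion at a single rate across the nuclear genome would give the same difference everywhere, but it was 0.195 points larger upstream of genes than in exons. The regions were read over each library's own cytosines, however, and over shared cytosines the nuclear difference was 0.0955 points. Differing coverage could thus make regions differ, and the test cannot decide on a single rate. A change in CHH methylation by ABA stays open as untested, and without spike-in DNA the nuclear difference cannot be read as an effect of ABA.

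CG methylation differed by -0.983 points between the ABA and NaOH libraries over the nuclear genome and was lower with ABA in introns (30.6% against 32.5%), but higher in exons (5.65% against 5.43%) and over gene bodies (8.49% against 8.33%). The region levels are over the cytosines each library covered. The ABA library covered more CG cytosines in introns (135537 against 131070) and fewer in exons (992523 against 1028689), so this mix can move the gene body level. Less complete conversion in the NaOH library would raise its organelle DNA too, but the apparent CG level of the mitochondrial genome was 0.133 points higher in the ABA library, which argues against it (chloroplast, 0.681% against 0.454%). Different cytosines covered by the libraries could account for part of it, but over shared cytosines the difference was still -0.549 points, which argues against coverage as the whole cause. At cytosines with at least 10 reads it was 0.0144 points. An effect of ABA on CG methylation stays open as untested with 1 library per treatment.

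ABA roots had more lower than higher genes. The NaOH control library as the whole cause is argued against, since the ratio of lower to higher genes was 1.32 with the H2O library, although it was 1.85 with NaOH. Scaling is argued against as well, since the smallest ratio under 3 rescalings was 1.72. A response to ABA may underlie the pattern, as a hypothesis. Both tests used the same ABA library, so a difference between plants or library preparations stays open.

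Other results were picked out because root and shoot moved in opposite directions under the same treatment, each with 1 library per group; the difference between the organs was not tested. Under ABA, Sb06g016540 had a log2 change of -3.86 in roots and 2.03 in shoots, and Sb01g002590 of -4.24 and 1.41. Under PEG, Sb05g026950 had a log2 change of -5.23 in roots and 1.29 in shoots, and its neighbour Sb05g026980 of -5.20 and 1.26. With the GB2 models these 2 IDs had the same FPKM in each library, for example 2.18 in PEG roots and 116 in H2O roots. Their reads cannot be told apart, so they do not count as 2 separate results. The precursor sbi-MIR167e had an ABA to NaOH ratio of 3.45 in roots and 0.552 in shoots, but 1.57 (interval 0.934 to 2.68) in roots with H2O as the control, and a log2 change of 0.58 in roots with the GB2 models, against 1.67.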

How the results depend on the processing

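Of the values recomputed with another setting, 188 stayed within 1.5 times the count or within the interval, 100 moved further and 2 methylation differences changed sign. In all, 5 had the opposite sign to the reported value: CG and CHG with at least 10 reads, and microRNA medians of root ABA (-0.02, reported 0.01) and shoot PEG (-0.06, reported 0.11) with median ratios set equal and of root PEG with GB2 models. The alternatives that left out genes listed at 0, kept the authors' contexts, kept shared cytosines, took microRNA precursors as a list or fitted limma were chosen after the data had been seen. No replicate could be paired or left out because each group has 1 library. With treatments paired across organs (organ as a block), limma called 5 genes higher and 0 lower with ABA at an adjusted p under 0.05 (2050 and 1758 unadjusted p under 0.05), and 1 and 0 with PEG (1427 and 391). With NaOH and H2O as 1 control group, limma called 564 and 441 with ABA, and 4 and 0 with PEG (1965 and 572 unadjusted p under 0.05). The organs are not known to be independent. Within an organ, with NaOH and H2O as 1 control group and 1 residual degree of freedom, limma called 2415 and 3215 genes (root ABA), 297 and 144 (root PEG), 2645 and 2154 (shoot ABA) and 2818 and 1141 (shoot PEG) at an adjusted p under 0.05. The error of these fits within an organ is the difference of the 2 control libraries, so a shift of a whole treated library counts as a change. Embryo, the shallowest library, limits detection most. The alternatives for files of reads without calls (read scalings, mapping score) were not run, since the bisulfite files give calls. Counts are given as higher and lower genes. Stricter folds and minimums leave fewer genes by construction; for the other moves the cause was not tested.

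With a fold of at least 4, the counts were 441 and 566 (root ABA), 218 and 47 (root PEG), 187 and 80 (shoot ABA), 247 and 40 (shoot PEG), 62 and 2 (root NaOH against H2O), 0 and 7 (shoot NaOH against H2O) and 86 and 33 (meristems). At that fold the overlaps, higher and lower in both, were 84 and 26 (ABA and PEG in roots), 106 and 12 (in shoots), 91 and 11 (root and shoot with ABA) and 65 and 1 (with PEG).

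With a pseudocount of 5, the counts were 741 and 1083 (root ABA), 427 and 137 (root PEG), 475 and 351 (shoot ABA), 420 and 127 (shoot PEG), 107 and 5 (root NaOH against H2O), 2 and 12 (shoot NaOH against H2O) and 166 and 60 (meristems). With a pseudocount of 0.1, lower genes numbered 447 (root PEG), 1112 (shoot ABA), 429 (shoot PEG, where 1346 were higher), 63 (root NaOH against H2O), 33 (shoot NaOH against H2O, where 55 were higher) and 412 (meristems).

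With GB2 models, which are more numerous, the counts were 1653 and 856 (root PEG), 1392 and 1128 (shoot ABA), 1386 and 578 (shoot PEG), 586 and 295 (root NaOH against H2O), 284 and 281 (shoot NaOH against H2O) and 971 and 519 (meristems), and 1969 genes were higher in root ABA. There the median of microRNA precursors was -0.16 for root PEG, against 0.28 with the reference models, and 0.19 for the meristems.

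Without the interval rule, 75 genes were lower in root NaOH against H2O, and in shoots 70 were higher and 65 lower. With an FPKM of at least 5, 15 genes were lower in root NaOH against H2O, 7 higher in shoot NaOH against H2O and 131 lower in the floral meristem. Genes lower in shoot PEG numbered 399 with upper quartiles set equal and 438 with median ratios set equal. Against NaOH roots, 572 genes were higher in PEG roots. Genes at least 4 times every other tissue numbered 19 in floral meristem, 3 in vegetative meristem, 816 in root and 720 in shoot.

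Methylation differences (ABA minus NaOH, points) were -1.28 at CG, -0.999 at CHG and 0.272 at CHH with at least 1 read per cytosine, and -0.549, -0.352 and 0.0955 over shared cytosines. With at least 10 reads, 0.0144 at CG and 0.367 at CHG had the opposite sign to the reported values, and CHH was 0.259. In the 1000 bases upstream of genes, in place of gene bodies, the CG, CHG and CHH levels were 12.7%, 7.62% and 1.19% in NaOH roots and 12.1%, 7.34% and 1.46% in ABA roots.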

Other observations

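The tests of exon number, of neighbouring genes and of gene body methylation were written before their results were seen; of the tests of genes listed at 0, that with GB2 was written before and those of expected reads after.

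Several of the named genes link organs and treatments. Sb09g027110 was at 1510 FPKM in embryos, 3777 in ABA roots and 547 in PEG shoots, and at 3.53 or less in the untreated seedlings, the meristems and flowers. With the GB2 models its levels were 649, 2186 and 340. Sb05g026950 and Sb05g026980 were at 418 and 388 FPKM in the vegetative meristem and 317 and 298 in the floral meristem, above any seedling library, and at 1.15 and 1.09 in flowers. With the GB2 models both IDs were at 395, 301 and 1.10 FPKM there, so they do not count as 2 separate results. Sb03g029390 was at 136 FPKM in both ABA roots and PEG shoots, 80.6 in embryos and 0.431 or less in the H2O and NaOH seedlings, but with the GB2 models at 50.3 in ABA roots, 45.3 in PEG shoots and 173 in embryos. Sb05g003480 was at 3389 FPKM in H2O shoots, 1479 in ABA shoots and 869 in flowers, and at 11.0 or less in roots (5141, 2171, 1948 and 28.7 with the GB2 models).

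The precursor sbi-MIR168, of the family that targets AGO1, had between 33 and 83 reads in the seedling libraries and 0 in embryo, and lay between 0.267 RPM in the floral meristem and 1.25 in PEG roots elsewhere. Of the 71 precursors, sbi-MIR159 had the highest read count with the reference models, 447 in the floral meristem. This did not hold with GB2. There sbi-MIR168 had 3040 reads in ABA roots and 2386 in H2O roots, and sbi-MIR159 had 1011 in the floral and 1206 in the vegetative meristem. In ABA against NaOH shoots sbi-MIR168 was past the size rule with GB2 (17.2 and 7.94 FPKM). Its log2 change there was 1.02, against 0.38 with the reference model.

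A hypothesis was that genes higher with ABA in both organs have few exons. The 346 such genes had a mean of 4.83 exons, at percentile 0.305 of matched random lists (5.04 to 6.08). The 216 genes lower in both had a mean of 3.24, so low exon number may go with response in either direction.

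A further hypothesis was that genes called in the root ABA comparison lie next to each other. Adjacent pairs called in the same direction numbered 637, against 263 to 325 in shuffles. Reads shared between neighbouring copies could give such pairs. Adjacency was therefore taken anew among the 14777 genes whose reads came out whole in both libraries. Such pairs numbered 356 there, against 186 to 237 in shuffles. Whether neighbours respond together, or are related copies with their own reads, stays open.

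Genes called in the root ABA comparison had low CG methylation over their bodies in NaOH roots, with a mean of 4.32% against 9.26% to 10.7% in lists matched on expression. Higher genes had 5.24% and lower genes 3.85%. Lists matched on exon number ranged from 8.00% to 9.28%, so exon number is not a likely sole cause. Of the called genes, 82.9% had a methylation value.

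Of the genes listed at 0 in 1 seedling library and at 10 FPKM or more in the other 3 of that organ, Sb02g022733 and Sb09g019930 would have been expected to give 176 and 531636 reads there, so sampling does not account for the 0. Sb09g019930 was also at 0 in the GB2 models, and Sb02g022733 has no model there, so genes above 0 in GB2 numbered 0. Both sets of models were quantified from the same reads with the same tool, so a locus that failed could be at 0 in both, and a failed estimate cannot be told apart from a missing transcript. The microRNA precursors sbi-MIR171e, sbi-MIR156c and sbi-MIR160b would have been expected to give at most 3.82 reads.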
